A study of Mus musculus with 6 samples.

How the data were processed

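RNA was measured by sequencing in 6 libraries of mouse intestine, taken at 5 months of age from animals whose strain is given as 129. Of these, 3 libraries came from Apc Min/+ mice and 3 from Apc Min/+ mice that also lacked Sirt7. Apc Min/+ mice carry a truncating allele of Apc, the negative regulator of Wnt signalling, and develop intestinal adenomas. Per the labels' protocols, RNA was extracted with Trizol and libraries were built with an Illumina TruSeq RNA kit. The labels do not say which part of the intestine was taken, whether it held tumour, or whether the libraries of a genotype came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

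The authors' deposited table held 1 column per library with a signal value per gene, which was the read count divided by 1 size factor per library and not scaled to a fixed total or by gene length. Per the submitters' processing notes, the build was mm10, and FastQC, TopHat, TopHat2 2.1.1, HTSeq 0.6.1p1 and DESeq2 were used, without roles, order or strand setting. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Per the file headers, the same table gave the authors' mean signal, a log2 fold change with its standard error, a Wald statistic (a score with no fixed range), and unadjusted and adjusted p-values. The sign of the authors' log2 values was checked against the sample columns. It had 20312 rows, and the lowest mean signal over the 6 libraries was 1.50. In 23 rows a date stood in place of the gene name, and these stayed unnamed.

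In every column, 100% of values were whole multiples of 1 step to within 0.01, so whole reads were recovered. In 2 columns, the third control and the second knockout, the step lay close to 1. Depth per library in recovered reads was 29234904, 28123962 and 29603348 in the control group and 27661396, 24987313 and 26610018 in the knockout group. Counting intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

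Genes with a value of at least 10 in at least 3 of the 6 libraries were tested, which left 16600. The test was limma 3.58.1 (lmFit, then eBayes with trend and robust estimation, in R 4.3.3) on log2(value + 1), with genotype as the sole term and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. Fold changes are knockout relative to control on the log2(value + 1) scale, which understates the change of low genes. Means and SDs are of the deposited signal over 3 libraries per group. Where a group had no reads, the fold was computed against a floor of 3 counts over the group. Where it had few reads, the ratio of means is given with an exact 95% interval for counting error.

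Before the data were examined, 38 gene lists were fixed, with the design, the alternatives and the rule for naming genes. Lists with at least 5 tested members were compared with all other genes by camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. A list was called at an adjusted p under 0.05. Camera with a correlation estimated per list, and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. The naming rule took Sirt7 and Apc, then the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 50 in the higher group and did not overlap between groups. Gene models named Gm with a number, ending in Rik, or named AC, AI, BC or RP with digits, and immunoglobulin or T cell receptor segments were left out. Clone names of other forms were not covered by this rule. Up to 4 members of each list followed, by smallest p. A few genes that this rule takes are not reported here.

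On simulated reads for 16402 genes with this layout, the limma step recovered 26% of genes changed 1.19-fold, 68% at 1.41-fold, 91.8% at 2-fold and 96% at 4-fold. It called 8 of 16174 unchanged genes. Only 200 drawn genes and the cell cycle list were changed there. In the real libraries far more genes passed, which loosens the Benjamini-Hochberg cut, so these shares need not hold for them. Camera recovered the 1 list that had been changed and called 0 of 36 others, on reads drawn independently per gene. On the real libraries camera called 12 to 20 lists in the 9 splits that mix the genotypes. These splits keep part of the genotype difference, so they do not show how often camera calls lists that did not change.

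Alternatives were the replicate number as a block, leaving out each library in turn with the same genes tested, TMM scaling, quantile normalization, no filter or a filter at 50, pseudocounts of 0.5 and 10, limma without robust estimation, and the 2 count models on recovered reads. The count models were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Positions are from GENCODE for GRCm38, the assembly also called mm10, matched by symbol for 15279 of the tested genes (92.0%). After the results had been seen, 9 further marker lists were used for the closing tests: stomach cells, upper intestine, ileum, Wnt-active epithelium, follicle stroma and M cells, follicular B cells, plasma cells, intraepithelial and lamina propria lymphocytes, and acinar digestive enzymes.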

Results

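The comparison addressed how loss of Sirt7, a nuclear and nucleolar deacylase of the sirtuin family, alters gene expression in the intestine of Apc Min/+ mice. It set 3 libraries of Apc Min/+ intestine (control) against 3 of Apc Min/+; Sirt7 -/- intestine (knockout). Library depth ranged from 24987313 to 29603348 recovered reads. Libraries of the same genotype were close to each other, with a common biological coefficient of variation of 0.056, yet all 6 such pairs differed by more than counting noise (mean chi-square per gene 3.98 to 7.80). The first principal component held 83.7% of the variance and separated the genotypes. Means are given as normalised reads ± SD over 3 libraries per group, and log2 fold changes with their SE.

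Sirt7 was low in all 3 knockout libraries. Its level was 2173 ± 64.5 in control and 228 ± 11.1 in knockout, so that 10.5% remained (log2 fold change -3.25 ± 0.07, limma adjusted p = 2.96e-20). An exact permutation test of the 3 against 3 libraries, two-sided, gave p = 0.1, the smallest value this design allows. In the authors' deposited table its log2 fold change was -3.22, with an SE of 0.082. Sirt7 lies on chromosome 11 (120618372 to 120625240, minus strand, mm10, protein coding) and its annotated end overlaps Mafg. Apc, on chromosome 18 (34220924 to 34322552, plus strand), stood at 3594 ± 196 in control and 3781 ± 82.7 in knockout (log2 fold change 0.07 ± 0.05, limma adjusted p = 0.18), and passed under quantile normalization (0.23, limma adjusted p = 0.00021). The fixed sirtuin list was not called (camera adjusted p = 0.29). Of its 7 members, Sirt6 rose from 275 ± 36.7 to 365 ± 19.3, Sirt1 and Sirt2 fell along with Sirt7, and 3 did not pass. Under quantile normalization Sirt6 no longer passed (limma adjusted p = 0.066).

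The 10 largest rises included the mucin Muc6, the gastrokines Gkn1 and Gkn3 and gastric lipase, and the 10 largest falls included the calcium channel gene Cacna1i, Pax5 and Adipoq. Muc6, the gel-forming mucin of gastric and duodenal glands (chromosome 7, 141633456 to 141655319), stood at 1.36 ± 1.18 in control and 10122 ± 571 in knockout. The ratio was 7444, with a 95% counting interval of 2869 to 26960. The gastrokine Gkn3 rose from 15.9 ± 1.34 to 8051 ± 588, and Gkn1 from 0.70 ± 0.61 to 2067 ± 83.4, a ratio of 2951 with an interval of 828 to 24707. Wfdc18 rose from 0.36 ± 0.62 to 2637 ± 129, a ratio of 7401 that rests on 1 control read, with an interval of 1373 to 302309. The other 6 leading genes had no reads in any control library. They were the selenium-independent glutathione peroxidases Gpx5 (1332 ± 37.1, at least 1285-fold higher) and Gpx6 (590.3 ± 32.4, at least 569.7-fold), the secreted BPI-fold proteins Bpifb5 (906 ± 98.1, at least 875-fold) and Bpifb1 (776 ± 103, at least 749-fold), gastric lipase Lipf (579.9 ± 72.2, at least 559.7-fold) and the chitinase Chit1 (464 ± 62.6, at least 448-fold). Gpx5 and Gpx6 are close relatives, so their separate values are uncertain.

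The leading falls included Pax5, the transcription factor of B cell identity (139.5 ± 35.5 to 6.49 ± 6.22), the low-affinity IgE receptor Fcer2a (479.6 ± 11.2 to 20.1 ± 9.16) and Cxcr5, which guides B cells into follicles (253 ± 28.4 to 12.2 ± 6.64). Ccr6, a chemokine receptor of B cells and other leukocytes, fell from 184 ± 27.6 to 7.44 ± 3.75. The adipokines Adipoq (87.1 ± 21.1 to 4.15 ± 6.34) and Cfd (107 ± 21.3 to 5.57 ± 4.59) fell as well. The remaining leading falls were the calcium channel gene Cacna1i (138 ± 41.6 to 3.07 ± 2.83), the endolysosomal channel gene Mcoln3 (266 ± 27.8 to 11.1 ± 4.69), the peptide transporter gene Slc15a2 (379.9 ± 40.4 to 16.7 ± 4.45) and a transcript known only by a clone name (128 ± 17.1 to 5.76 ± 2.15). All of these genes passed in limma, with adjusted p-values from 1.61e-25 for Gkn3 to 0.0057 for Pax5.

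**Figure D1:**
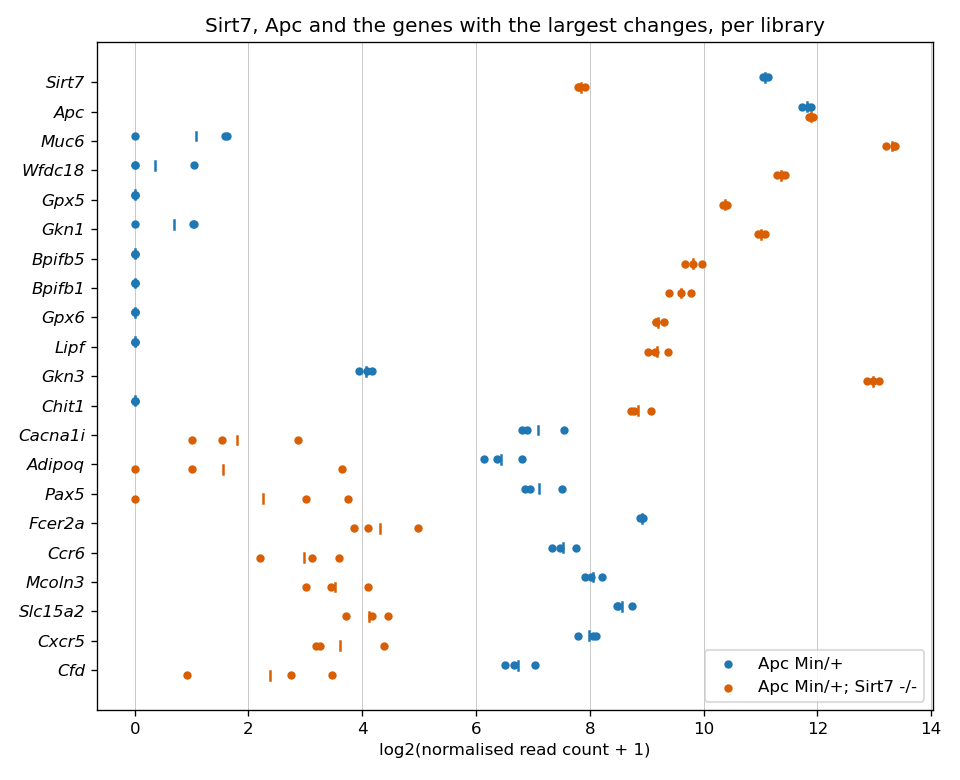
Level of Sirt7, Apc and 19 of the 20 genes with the largest changes, as log2(normalised reads + 1) on the horizontal axis. Points are single libraries (blue, 3 Apc Min/+; orange, 3 Apc Min/+; Sirt7 -/-), vertical ticks are group means, and apart from Apc the groups do not overlap for any gene shown.

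In all, 10381 of 16600 tested genes passed, of which 5248 rose and 5133 fell. Changes of over 2-fold were seen for 2763 genes, with 1621 higher and 1142 lower, while under quantile normalization 1320 were higher and 1346 lower. The authors' deposited table lists 9998 genes at an adjusted p under 0.05, 5066 higher and 4932 lower. The groups did not overlap for 66.5% of genes, where chance gives 10%. Of the 38 fixed lists, 37 could be tested and camera called 23, with 12 higher and 11 lower in knockout. In the 9 splits of the libraries that mix the genotypes camera called 12 to 20 lists, but these splits keep part of the genotype difference and give no chance level. With an estimated correlation 6 calls held: cell cycle, DNA repair, ribosome biogenesis, ribosomal proteins, absorptive enterocyte, and T and NK lymphocyte. Of the 673 tested members, 578 passed over all genes and 586 passed when adjusted over the list alone.

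Wnt targets and intestinal stem cell genes rose together, with 21 of 24 members higher, 1 lower and a median log2 fold change of 1.87 (camera adjusted p = 1.4e-09). The call was lost with an estimated correlation (adjusted p = 0.058). Notum, a secreted Wnt deacylase, rose from 10.3 ± 0.73 to 1538 ± 23.1, and Lgr5, the marker of crypt base stem cells (chromosome 10, 115450311 to 115587780), from 90.5 ± 12.9 to 1826 ± 112. Cd44 rose from 831 ± 26.8 to 4468 ± 183 and the progenitor transcription factor Sox9 from 211 ± 13.8 to 1881 ± 182. Tcf7 was the member that fell (-0.27). Adjusted over the list alone, 22 members rose. Markers of absorptive enterocytes were lower in the same libraries (median -0.92).

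All 29 cell cycle genes rose (median 0.93, camera adjusted p = 3.7e-10, adjusted p = 0.043 with an estimated correlation). Top2a, which untangles DNA for mitosis, rose from 2004 ± 103 to 4693 ± 102, and the proliferation marker Mki67 from 2672 ± 182 to 5093 ± 225. Mcm4 and Ccna2 rose by 1.07 and 0.93 on the log2 scale. Among DNA repair genes 25 of 32 rose and 0 fell in limma, with 7 not passing (median 0.72, camera adjusted p = 4.7e-07, adjusted p = 0.043 with an estimated correlation). Apex1, of base excision repair, rose from 389 ± 28.2 to 898 ± 10.7, and Xrcc5, of end joining, from 186 ± 7.58 to 487 ± 41.0. Rif1 rose by 0.95. The cell cycle list moved in the same direction in the same libraries.

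Genes of ribosome production rose as well. In the ribosome biogenesis list 22 of 23 rose (median 0.76, camera adjusted p = 5.7e-08, adjusted p = 0.043 with an estimated correlation), among them the nucleolar proteins Npm1 (5144 ± 138 to 10318 ± 219) and Ncl (6103 ± 185 to 11446 ± 244). Nop56 rose by 1.07 and Ddx21 by 0.86. Of 28 ribosomal protein genes 26 rose, and 27 when adjusted over the list alone (median 0.33, camera adjusted p = 3.7e-06, adjusted p = 0.043 with an estimated correlation). Rplp0 rose by 0.69, Rpl7 by 0.51, Rpl3 by 0.48 and Rps3 by 0.46, all on the log2 scale. Mitochondrial ribosome and unfolded protein response genes were not called (6 of 17 rose, 3 fell, camera adjusted p = 0.31). Of these, Hspd1 rose from 10097 ± 269 to 11710 ± 281, Lonp1 and Mrps18b rose by 0.40, and Mrpl12 fell by 0.25. Mrpl12 no longer passed under quantile normalization (limma adjusted p = 0.068).

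The p53 targets went both ways, with 11 of 22 higher and 9 lower (median 0.08, camera adjusted p = 0.73). The cell cycle inhibitor Cdkn1a fell from 7423 ± 113 to 4572 ± 65.9, the pro-apoptotic Pmaip1 from 5160 ± 79.9 to 2433 ± 116 and Gadd45a from 1749 ± 10.4 to 877 ± 19.9. Plk2 rose from 230 ± 11.8 to 685 ± 43.6. Camera placed this list lower than other genes although its median lay above 0, and with the filter at 50 the median was -0.06. The endoplasmic reticulum stress list, with 4 of 21 higher and 12 lower, was not called (camera adjusted p = 0.055). It was called without the third control library (camera adjusted p = 0.035). Herpud1 fell from 8098 ± 194 to 3744 ± 58.0, Trib3 from 831 ± 30.1 to 305 ± 9.41, and Dnajb9 and Edem1 by 0.86 and 0.57. Immediate early and heat shock genes were not called (7 of 18 rose, 9 fell, camera adjusted p = 0.73). Zfp36, Hsph1 and Hspa1a fell by 0.99, 0.67 and 0.95, and Ier3 rose by 1.38.

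Genes of the mature absorptive epithelium fell. All 22 absorptive enterocyte genes were lower (median -0.92, camera adjusted p = 3.7e-10, adjusted p = 0.043 with an estimated correlation). The sodium-glucose transporter Slc5a1 (chromosome 5, 33104219 to 33162870) fell from 146376 ± 1666 to 61722 ± 232, the brush border peptidase Anpep from 202452 ± 2768 to 95662 ± 3103, the lipoprotein assembly gene Mttp from 106486 ± 1214 to 50342 ± 2009, and Apoc3 from 19499 ± 666 to 5116 ± 404. Of 24 xenobiotic metabolism genes 23 fell (median -0.94, camera adjusted p = 1.9e-09), a call lost with an estimated correlation (adjusted p = 0.24). Gstm1 fell from 10565 ± 350 to 2525 ± 262 and Ces2a from 9679 ± 187 to 4314 ± 241, while Cyp3a13 and Aldh1a1 fell by 1.11 and 0.93. Gstm1 and Cyp3a13 have close relatives, so their values are uncertain. All 27 oxidative phosphorylation genes fell, each by less than 2-fold (median -0.55, camera adjusted p = 2.2e-08, adjusted p = 0.24 with an estimated correlation). Sdha fell from 19303 ± 624 to 12294 ± 624, and Sdhb, Sdhd and Cox5a by 0.60, 0.58 and 0.59.

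Of 22 genes of peroxisome proliferator signalling and fatty acid oxidation, 16 fell and 5 rose (median -0.43, camera adjusted p = 0.0054, adjusted p = 0.36 with an estimated correlation). The fatty acid transporter Slc27a4 fell from 34985 ± 1421 to 15829 ± 680.5 and Creb3l3 and Cd36 fell by 0.93 and 0.76. This call was also lost under quantile normalization (camera adjusted p = 0.051). Cholesterol synthesis genes rose, 14 of 19 with 2 lower (median 0.51, camera adjusted p = 0.00014, adjusted p = 0.058 with an estimated correlation). Sqle rose from 1284 ± 26.8 to 2563 ± 135, and Idi1 and Lss rose by 0.75 and 1.02. Glycolysis and HIF targets were not called (10 of 22 rose, 9 fell, camera adjusted p = 0.80). Hexokinase genes Hk2 (861 ± 44.4 to 3241 ± 154) and Hk1 (593 ± 2.88 to 1281 ± 60.9) and the glucose transporter Slc2a1 (461 ± 24.7 to 1407 ± 67.1) rose, and Pfkfb3 fell by 1.28. The median of this list was -0.10 and its mean 0.21, and under quantile normalization its median was 0.17 and it was called higher (camera adjusted p = 0.013). Circadian clock genes fell, 12 of 15 with 0 higher in limma (median -0.60, camera adjusted p = 0.00020, adjusted p = 0.11 with an estimated correlation). The clock output genes Dbp and Tef fell by 1.09 and 0.62, and Nr1d1 and Per2 by 0.85 and 0.76.

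Lymphocyte genes were lower in knockout. Of 13 B lymphocyte and plasma cell genes 12 fell, each by over 2-fold (median -3.52, camera adjusted p = 2.2e-05), a call lost with an estimated correlation (adjusted p = 0.24). The B cell surface gene Ms4a1 fell from 1002 ± 42.2 to 73.7 ± 16.9 and Cd79a, of the B cell receptor complex, from 1345 ± 30.4 to 216 ± 34.7. Sdc1, carried by plasma cells but also by epithelium, rose from 1774 ± 24.9 to 4817 ± 119. All 14 T and NK lymphocyte genes fell by over 2-fold (median -1.71, camera adjusted p = 4.7e-07, adjusted p = 0.045 with an estimated correlation). Cd8a fell from 1047 ± 27.9 to 332 ± 33.0, Cd4 from 414 ± 27.6 to 117 ± 8.67, and Cd3g and Lck fell with log2 fold changes of -1.67 and -1.59. All 7 MHC class II genes fell, each by less than 2-fold (median -0.63, camera adjusted p = 0.00059, adjusted p = 0.11 with an estimated correlation). Cd74 fell from 21429 ± 512 to 13841 ± 165, and H2-Eb1, H2-Ab1 and the class II transactivator Ciita by 0.72, 0.58 and 0.98.

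Inflammatory and antimicrobial genes mostly rose, 17 of 25 with 6 lower (median 2.41, camera adjusted p = 0.014, adjusted p = 0.22 with an estimated correlation). Lipocalin Lcn2 rose from 46.6 ± 2.01 to 735 ± 32.3, Duoxa2 from 1150.1 ± 56.2 to 3797 ± 387 and Saa3 from 29.4 ± 3.21 to 513 ± 54.3. The antimicrobial lectin Reg3g fell from 148080 ± 9078 to 47432 ± 2059. Saa3 and Reg3g have close relatives. Of 28 interferon response genes 15 rose and 4 fell, or 17 and 4 adjusted over the list alone (median 0.24, camera adjusted p = 0.0087, adjusted p = 0.13 with an estimated correlation). Ifi44 rose from 143 ± 23.0 to 1064 ± 145, and Oas2, Ifit2 and Ifit3 by 1.81, 1.87 and 1.00. Mast cell and eosinophil genes rose, 7 of 8 with 1 lower (median 2.37, camera adjusted p = 0.016, adjusted p = 0.26 with an estimated correlation). The mucosal mast cell proteases Mcpt2 (79.9 ± 8.08 to 820.3 ± 125) and Mcpt1 (221 ± 33.7 to 984 ± 135), whose sequences are close, and Kit (log2 fold change 0.72) rose, while the eosinophil gene Prg2 fell by 1.56. With the filter at 50 this list was no longer called (camera adjusted p = 0.092). Macrophage and neutrophil genes were not called (3 of 16 rose, 9 fell, camera adjusted p = 0.082). Lyz2, Csf1r and C1qa fell by 0.90, 0.83 and 0.69 and Cd14 rose by 1.09.

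Pancreatic acinar genes had the highest median of any tested list, 3.92, with 18 of 19 higher (camera adjusted p = 7.9e-08, adjusted p = 0.091 with an estimated correlation). Pnliprp1 rose from 14.8 ± 3.06 to 981 ± 43.6, the elastase gene Cela1 from 203 ± 9.03 to 1399 ± 137, and the amylase gene Amy2a5 by 4.61. Its near copy Amy2b, annotated as an unprocessed pseudogene, rose by 3.82, so the separate values of Amy2a5 and Amy2b are uncertain. Paneth cell genes were not called (8 of 13 rose, 3 fell, camera adjusted p = 0.063), but were called without the third control library (camera adjusted p = 0.049) or without the second knockout library (camera adjusted p = 0.043). Within this list Pla2g2a, an antimicrobial phospholipase that is disrupted in several inbred strains and modifies tumour number in Apc Min/+ mice, rose from 47.7 ± 4.51 to 2612 ± 75.4. It lies on chromosome 4 (138831857 to 138835186) and is annotated as a polymorphic pseudogene, so its rise need not mean more working enzyme. Whether the mice of either group carry a working copy was not tested. Mmp7 rose from 363 ± 10.9 to 4148 ± 503, Mptx2 and Nupr1 by 2.07 and 1.43. Goblet cell genes went both ways (7 of 12 rose, 5 fell, camera adjusted p = 0.31), with Agr2 rising from 3626 ± 132 to 15279 ± 173, Muc2 from 22564 ± 305 to 36007 ± 1777 and Spink4 by 1.58, and Zg16 falling by 0.61. Of 18 enteroendocrine genes 12 fell and 0 rose in limma, with 1 higher when adjusted over the list alone (median -0.49, camera adjusted p = 0.0087, adjusted p = 0.24 with an estimated correlation). The incretin gene Gip fell from 3728 ± 11.02 to 1821 ± 178, and Sct, Sst and Cck by 1.03, 0.87 and 0.78. With DESeq2 values this list was no longer called (camera adjusted p = 0.064). Tuft cell genes were not called (2 of 12 rose, 6 fell, camera adjusted p = 0.14), with Avil rising by 2.45 and Fyb, Trpm5 and Ltc4s falling (log2 fold changes -1.12, -0.79 and -1.31).

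Neither regional list was called. Of 14 small intestine genes 9 fell and 4 rose (median -0.40, mean 0.19, camera adjusted p = 0.077), with Apoa4 falling from 474303 ± 20641 to 166644 ± 8843 and Sis, Mep1b and Slc2a2 by 0.91, 0.89 and 1.03. Of 10 colon genes 6 fell and 3 rose (camera adjusted p = 0.35), with Cyp2c55, Saa1 and B3galt5 falling (log2 fold changes -1.34, -4.16 and -1.29) and Mptx1 rising by 1.45. Fibroblast and matrix genes rose, 12 of 17 with 2 lower (median 0.41, camera adjusted p = 0.0056, adjusted p = 0.11 with an estimated correlation), led by Col1a1 (643 ± 37.4 to 2171 ± 200.0) and Col3a1 (2609 ± 217 to 5271 ± 137). Sparc and Col1a2 rose by 0.91 and 0.89. Genes of mesenchymal transition and invasion rose, 12 of 19 with 5 lower (median 0.73, camera adjusted p = 0.018, adjusted p = 0.19 with an estimated correlation). Osteopontin, Spp1, rose from 21.4 ± 6.72 to 1891 ± 172, and the matrix proteases Mmp13 and Mmp14 and fibronectin, Fn1, by 2.60, 1.73 and 1.17. Vim, Zeb1 and Zeb2 of this list fell by 0.18, 0.54 and 0.38, and were named after their values were seen. Smooth muscle genes fell, 10 of 14 with 2 higher (median -0.41, camera adjusted p = 0.0061, adjusted p = 0.24 with an estimated correlation), and were not called under quantile normalization (camera adjusted p = 0.073). Myh11 fell from 17519 ± 599 to 11126 ± 487, and Mylk, Myl9 and Synpo2 by 0.63, 0.56 and 0.71. Adipocyte genes fell, 8 of 10 with 1 higher (median -1.07, camera adjusted p = 0.0047, adjusted p = 0.21 with an estimated correlation), with Cidec, Lipe and Fabp4 falling by 1.16, 0.99 and 0.71. Cidec and Lipe stood at 3957 and 4294 in control, against 87.1 for Adipoq and 107 for Cfd. Adipoq and Cfd fell further (log2 fold changes -4.89 and -4.36). Whether all these falls came from adipocytes was not tested. Endothelial genes were not called (7 of 14 rose, 4 fell, camera adjusted p = 0.31). Cdh5 and Tek rose by 1.43 and 1.39, Pecam1 fell by 0.41, and Prox1, also in the Wnt list, rose from 11.5 ± 6.71 to 783 ± 31.1. Enteric neuron and glia genes were not called (2 of 17 rose, 4 fell, camera adjusted p = 0.22), with Vip and Ret rising by 0.75 and 0.82 and Uchl1 falling by 0.56. Only 1 erythrocyte gene could be tested, Alas2, which rose from 14.5 ± 5.64 to 70.5 ± 12.3.

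**Figure D2:**
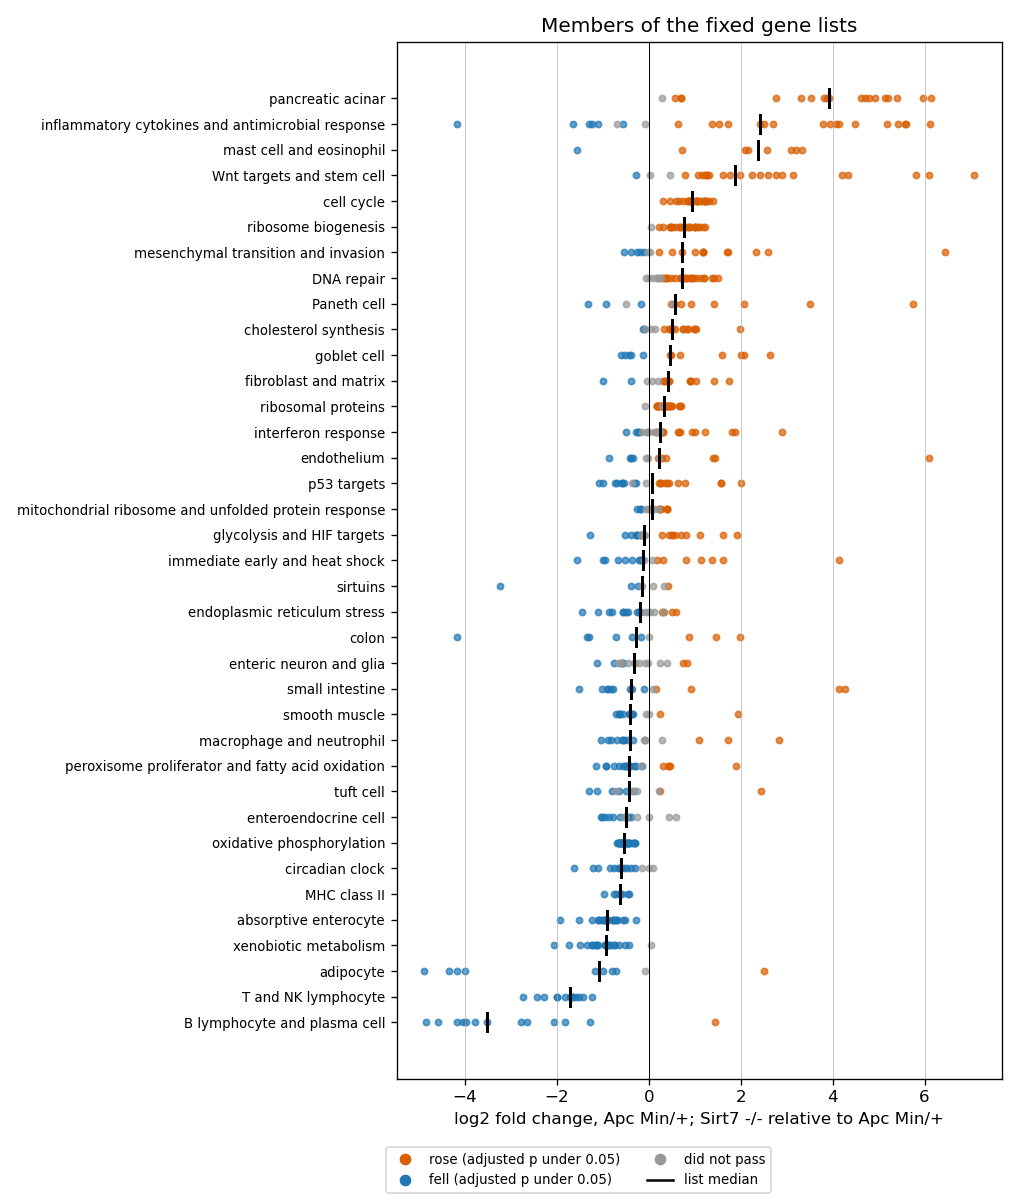
Log2 fold change, knockout relative to control, on the horizontal axis for every tested member of the 37 tested lists, 1 list per row ordered by median. Points are genes (orange rose, blue fell, grey did not pass, limma), black ticks are list medians, which run from -3.52 for B lymphocyte and plasma cell to 3.92 for pancreatic acinar.

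The median log2 fold change of all tested genes was 0.01. The 20 most abundant genes took 13.9% to 14.4% of reads in control libraries and 9.5% to 9.7% in knockout libraries.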

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

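Sirt7 kept its direction and passed under every alternative, with a log2 fold change between -3.30 (quantile normalization) and -3.20 (pseudocount 10). Without each library in turn it ranged from -3.29 to -3.22. The count of genes that passed was 9672 to 9869 without each library in turn, 9484 to 10743 under the other scalings, filters, pseudocounts and models, and 11268 at an adjusted p under 0.1. Requiring a log2 fold change over 1 as well lowered it to 2763, by construction. Of the 10381 genes, 10213 were shared with edgeR, which called 10374, and 9897 with DESeq2, which called 9906. Quantile normalization moved the share of calls that were higher from 50.6% to 46.4%, and over 2-fold the 1621 higher and 1142 lower became 1320 and 1346, with 8982 shared calls and 70 calls of opposite direction. No scaling moved the median of all genes by over 0.1.

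The replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at 0.0003, 0.036 and -0.006. With the number as a block, 10402 genes passed, 10289 of them shared, and Sirt7 stayed at -3.25 (adjusted p = 8.5e-17).

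The count of called lists was the result most tied to the method. Against 23, with 12 higher and 11 lower, camera with an estimated correlation called 6, with 4 higher and 2 lower. This setting allows for genes of a list that vary together. Fry called all 37 tested lists, 17 higher and 20 lower, because it asks whether a list moves at all and not whether it moves more than other genes. Without each library in turn, 23 to 25 lists were called. With edgeR or DESeq2 values 30 and 28 were called, of which 7 and 6 had not been called in the main fit. Some lists given above as not called are therefore called with those values. For the named genes, 2685 values under the alternatives kept their direction and side of the threshold, 1 (Apc) came to pass and 2 (Sirt6, Mrpl12) ceased to. For single lists the counts were 608, 37 and 21. The cause was not tested for any of these. Depth limits the low genes, where a group of 3 libraries with no reads gives only a lower bound. Replicate spread limits small changes. In the simulation, where few genes were changed, 26% of 1.19-fold changes were recovered.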

Other observations

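The marker lists and genes below were chosen after the main results had been seen, and the tests of stomach tissue, of a proximal piece, of an even loss of lymphocytes and of pancreas tissue were written after the values they measure. For the proximal piece, the genes near Sirt7 and the single RNA pool, the rule for a verdict was also made stricter after the values were seen, and all 3 were then left open. Under the earlier rules the first 2 would have been argued against and the single pool would have been met. The stomach test first used only the 5 genes past the filter, with a median of 4.56. Since 3 of these pass it through the knockout libraries alone, that median is set aside. The median used instead has a like limit, because only 7 of the 14 listed genes are in the deposited table. Of these, Atp4b had reads in knockout libraries only. The test of an even loss first used lists assembled from the results, and was replaced by lists fixed beforehand. Of the tested members, 7 of 10 follicular B cell genes, 7 of 13 intraepithelial and lamina propria genes, 5 of 10 plasma cell genes, 4 of 13 upper intestine genes, 2 of 7 ileum genes and all 11 acinar enzymes are also in the fixed lists. Control intestine expressed 2 of 5 stomach cell genes and 1 of 11 acinar enzymes at a mean of at least 50, and most genes of the other lists.

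The gene next to Sirt7 fell almost as far as any abundant gene. Pcyt2, which makes CDP-ethanolamine for membrane phospholipids, ends 0.436 kb from Sirt7 on chromosome 11 (120610087 to 120617936). It fell from 11843 ± 663 to 2377 ± 239 (SD, n = 3 libraries per group), so that 20.1% remained (limma adjusted p = 3.4e-15). Of 1090 genes with a control mean of at least 5000, 2 fell that far, Pcyt2 included. Mafg, whose end overlaps Sirt7, stood at 1477 ± 71.7 and 1522 ± 28.1, and Notum lies 28.5 kb away. Within 200 kb, 28 genes were tested, of which 11 rose, 7 fell and 7 changed over 2-fold (25%).

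Most iron genes of the upper intestine list rose. The ferric reductase Cybrd1 went from 701 ± 5.72 to 2436 ± 387, the exporter Slc40a1 from 3864 ± 269 to 10553 ± 1500.3 and the importer Slc11a2 from 3498 ± 187 to 6504 ± 800. Tfrc went from 4925 ± 231 to 6475 ± 44.8 and Hmox1 from 116 ± 11.9 to 217 ± 22.3 (n = 3 libraries per group, all limma adjusted p under 0.05). The iron oxidase Heph, which works with Slc40a1, fell from 12197 ± 382 to 8501 ± 64.2. Cyb5r3, a reductase in the same list, fell from 14734 ± 388 to 9448 ± 801. The intrinsic factor receptor genes Cubn (6639 ± 306 to 1865 ± 191) and Amn (1869 ± 202 to 811 ± 77.1) fell. The ileal bile acid genes Fabp6 (9.66 ± 2.12 to 184 ± 19.96) and Slc10a2 (14.97 ± 6.58 to 293 ± 55.9) rose from low levels, while the bile acid exporter genes Slc51a (5380 ± 32.4 to 4091 ± 32.0) and Slc51b (1561 ± 133 to 822 ± 38.2) and the bile acid receptor Nr1h4 (1145 ± 45.6 to 1000.4 ± 26.8) fell. Of 10 plasma cell genes 7 fell and 2 rose (median -0.92, exact sign test over genes, p = 0.34). Jchain, Mzb1, Tnfrsf17, Irf4 and Derl3 fell by over 2-fold. Prdm1 and Xbp1 fell by 0.55 and 0.26, Sdc1 and Fkbp11 rose and Ssr4 did not pass. All 10 follicular B cell genes fell (median -4.04). The difference between these lists was not tested. All 6 libraries had the values of male tissue, with Xist at 8.26 to 19.8 and the Y-linked Ddx3y at 1642 to 2009.

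The gastric genes among the largest rises and most pancreatic acinar genes were higher in the knockout libraries, though control intestine already expressed some acinar genes (Cela1 at 203, Clps at 185), and stomach tissue, a more proximal piece, pancreas tissue and more adenoma-like epithelium were weighed for them. Of the 14 listed stomach cell genes, 7 were in the table, and these had a median log2 fold change of 1.76. No filter on level was applied beyond presence in the table. That median leaves out the absent genes, whose levels are not known, so it cannot decide the question. The genes present went apart. In knockout libraries Pgc, Tff1 and Atp4a rose to 257, 353 and 46.8, and the untested Atp4b and Gif stood at 3.98 and 3.83. Aqp4 and Bhlha15, which control intestine expressed at 307 and 183, fell. Stomach tissue was therefore neither shown nor excluded. Upper intestine genes went both ways (7 of 13 rose, 4 fell, median 0.15), as did ileum genes (2 of 7 rose, 5 fell, median -0.39), so a difference in position along the gut cannot be told apart from none. All 11 acinar digestive enzymes rose (median 4.78), but their median gain was 0.094 of that of Pnliprp1 (90.4 against 966 reads), and with no pancreas profile at hand this leaves pancreas tissue open. A second list of Wnt-active epithelium, without genes of the first, rose in 10 of 12 and fell in 1 (median 1.30, exact sign test over genes, p = 0.0063). That test takes the genes as independent and does not measure the spread between libraries. The rise is what a larger share of adenoma-like epithelium would give. The first Wnt list had already risen in these libraries, so a rise of related genes was likely beforehand. Higher Wnt target levels without more adenoma would give it too, so the test cannot tell these apart. It does not tie the gastric or acinar genes to such epithelium, and gland-type differentiation within that tissue was not tested.

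B cell and follicle genes fell in the knockout libraries. An even loss of all lymphocytes is argued against, because in the lists fixed beforehand the 14 T and NK genes had a median log2 fold change of -1.71 and the 13 B lymphocyte and plasma cell genes -3.52, a difference of 1.81, and 8 of the latter fell further than any of the former. Within libraries the gap between the list medians, T and NK minus B and plasma cell, was 2.24 ± 0.28 higher in knockout on the log2 scale (SE over 3 libraries per group), and the groups did not overlap. The 13 intraepithelial and lamina propria genes, listed later, had a median of -1.67. Follicle stroma and M cell genes fell with the B cells, 10 of 11 with 1 higher, Tnfrsf11b (median -1.97), while Cxcl13 went from 805 to 107 and Ccl20 from 653 to 136. This list is not fully separate from the B cell genes, because lymphocytes themselves express Lta, Ltb and Spib (log2 fold changes -3.81, -2.94 and -1.95). Fewer lymphoid follicles in the pieces taken may explain the fall, but a loss of B cells would lower part of the list by itself. Whether that reflects where the tissue was cut, tumour replacing mucosa or an effect of Sirt7 was not tested.

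Libraries of 1 genotype differed so little that they may come from 1 RNA pool or animal. Genes of follicles, which lie patchily along the gut, should vary between separate pieces. The 10 follicular B cell genes had a median biological coefficient of variation (edgeR, counting noise removed) of 0.088 among control libraries, against 0.048 for other genes of like level. In knockout libraries, where they were low, it was 0.39 against 0.14. Some low genes, seen after the fact, differed within control, with Tff1 at 13.4, 10.7 and 0, Aqp5 at 21.7, 18.2 and 0 and Wfdc2 at 29.9, 33.1 and 2.01. The follicular B cell genes also shifted together, with sums of 5735, 6072 and 6592 in control and 291, 403 and 465 in knockout (323, 400 and 488 reads). These sums varied more than counting allows (chi-square test, p = 1.1e-13 and 2.6e-10), and of 10000 drawn sets of other genes of like level, 3 in control and 0 in knockout varied as much. Such shifts speak against 1 pool sequenced 3 times, but effects of library preparation that follow gene length or GC content were not tested, and separate pieces of 1 animal would shift in this way too, so the question stays open. The adjusted p-values rest on this spread.

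Among tested genes within 5 Mb of Sirt7, 14.5% changed over 2-fold, against 16.6% elsewhere (20 of 138, Fisher's exact test, p = 0.57), so a strain haplotype carried with the allele was neither shown nor excluded. Within 5 Mb of Pla2g2a the share was 19.4% against 16.6% (25 of 129, Fisher's exact test, p = 0.40), which leaves a haplotype there open as well.

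The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In limma the real split gave 10381 genes and 2763 over 2-fold, and the highest of the other splits gave 0 for both. For lists the real split gave 23 and the highest of the others 20. Every other split mixes the genotypes, which moves most of the genotype difference into the spread within groups and leaves part of it between them, so these counts give no chance level.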
